A study of Mus musculus with 6 samples.

How the data were processed

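Methylated DNA immunoprecipitation sequencing (MeDIP-seq) was carried out on 6 libraries of mouse cells, 1 per group: embryonic fibroblasts (MEF), MEF-derived induced neurons at 1, 3, 5 and 7 dpi, and primary hippocampal neurons. Per the labels, a further library of input DNA served all 6. The labels do not spell out dpi, and it is used here only as their name for the 4 times. Groups were taken from the sample titles for induced neurons and from the cell type labels for MEF and primary neurons. The submitters' processing notes name CASAVA, Bowtie2 2.1.0 and the mm10 genome build. The peak caller, the test behind the comparisons and their thresholds are not given in the sources used here. Library totals, the input library's reads and signal tracks were not analysed here.

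The first kind of file is a peak list that the authors called separately in each library. For every peak the deposited lists give a position, a length, the tag count at the summit, a fold enrichment, the −log10 of a q-value, a class (promoter, gene body or intergenic) and an assigned gene. These scores are the authors' own values for each peak and were used only to describe and rank peaks within a library. Entries that repeat a peak for a second gene were counted once when peaks were counted.

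The second kind is a set of tables of promoter regions, 2 for each of the 5 comparisons with MEF, which hold regions within 2 kb of a transcription start site (TSS) that the authors listed as higher or lower than MEF. In the comparisons of 1, 3 and 5 dpi, the deposited values of both libraries are whole read counts. In the comparisons of 7 dpi and of primary neurons the authors deposited a scaled signal: 1 read is worth 1.15 in the 7 dpi library and 0.866 in MEF, and 0.966 in primary neurons and 1.04 in MEF. Dividing by these steps gave whole reads for 100% of the values up to 20 reads, within 0.1 read. Folds below use the authors' scaled values, and the reads named are whole reads. The authors' log2 fold changes, p-values and q-values stand in the same tables. The deposited p-values equal those of a G-test of the 2 values against an even split, with a median difference of at most 0.254%. At least 98.1% of the regions in each list have a p of at most 0.0001, which needs 11 reads where the other library has 0. The smallest number of whole reads in the higher library was 11 at 1, 3 and 5 dpi in both directions. At 7 dpi it was 10 for regions higher than MEF and 13 for regions lower than MEF, and in primary neurons 12 and 11, so the scaling set different limits for the 2 directions.

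Each group has 1 library, so there is no replicate check, no SD and no p-value of differences between conditions. A test on the reads of 2 libraries compares those libraries, not the conditions. Intervals are exact Clopper-Pearson 95% intervals. A fold against 1 to 3 reads is given with its exact counting interval. A fold against 0 reads, written as at least, is a bound with that library set to a floor of 3 reads. The bound takes the reads of the higher library as they are. It leaves out their counting error and cannot be compared with the lower end of an interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The tables list only regions that passed the authors' test, so they do not give values for a promoter that was not listed.

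Peak sets were compared by overlap of at least 1 bp with bedtools 2.31.1. Everything else was computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Gene lists were fixed before the data were examined. Of the 21 lists, 15 are lists of symbols: neuronal fate transcription factors, neuronal structure and synapse, neuronal channels and receptors, fibroblast and mesenchymal genes, DNA methylation machinery, germline, pluripotency, imprinted, muscle, astrocyte, oligodendrocyte, microglia and myeloid, endothelial, cell cycle and housekeeping genes. The other 6 are families found by symbol: HOX clusters, clustered protocadherins, olfactory and vomeronasal receptors, KRAB-like zinc finger genes, keratins with keratin-associated proteins, and histone clusters. The number of members listed in a comparison was placed among 10000 random lists of the same size drawn from 26220 genes with a curated RefSeq transcript, and is given as a percentile. Lists in the upper or lower 2.5% are said to stand apart. Of the 11454 gene identifiers in the promoter tables, 11411 were found in the reference and 11401 in that background. The tables give no CpG class, so random lists were not matched on it. They were not matched on gene length either.

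Genes shared by comparisons were set beside the number that independent lists of the same sizes would share (n1 × n2 / N). All 5 comparisons use the same MEF library, which cannot be split. Unchanged libraries simulated against 1 MEF library gave lists of at most 74 genes, too short to say how many genes lists of the observed size would share, and were not used. The step fit, the overlap, the percentile and the length of regions were tested on simulated data. All 4000 simulated scaled reads were recovered (100%). Of 200 lists without enrichment 3% exceeded the upper limit, and of 200 lists with 10 of 50 members planted 100% did. With windows of 200 bp in steps of 20 bp, 12 reads at 1 position gave a region of 380 bp in 100% of 300 cases, against 2.34% for 18 reads spread over 300 bp. The window size used by the authors is not given in the sources used here, and the deposited tables hold no read positions, so reads stacked at 1 position are inferred from this length.

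The genes named were set by a rule written before the data were examined. Per comparison it takes the 5 lower and 5 higher genes with the largest fold (ranked by the bound or by the ratio to at least 3 reads), without predicted genes, Riken clones, olfactory and vomeronasal receptors and small RNAs, and the 2 listed members with the largest fold of each list. Over comparisons it takes up to 10 genes listed in the same direction in all 5 and up to 10 at all 4 times, and per library the 3 annotated genes with the highest peak score. Other genes are said to have been chosen after their values were seen. Genes in several near-identical copies, such as Erdr1, Sfi1, Speer7-ps1, Tmem181b-ps and the olfactory receptors, may share reads with their copies and are uncertain.

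Alternatives fixed beforehand were stricter scores, q-values and p-values, autosomes alone, larger overlaps, equal numbers of peaks, a fold of at least 4, distinct genes, at least 10 reads, folds rescaled by 1.5, overlap of regions in place of genes, promoter peaks alone, and a background of genes in any table. Chosen after seeing the data were an equal minimum of 13 reads in both directions, the test on unscaled reads, leaving out regions of 380 bp, and leaving out the 7 dpi or the primary neuron comparison from the shared genes.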

Results

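To follow DNA methylation while fibroblasts were converted into neurons, methylated DNA was captured and sequenced in 6 groups of cells from ICR mice, with 1 library each. MEF, primary fibroblasts of mouse embryos, were the negative control. Induced neurons made from them were sampled at 4 times, 1, 3, 5 and 7 dpi. Primary neurons from the hippocampus of 1-day-old pups were the positive control. The depth behind a promoter value is the number of reads in its region: the median in the higher library was 12 to 14 reads or scaled reads in every list, so most values rest on few reads. No difference reported here has a replicate check.

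Peaks of captured DNA lay mostly outside promoters in all 6 libraries, with 70.9% to 77.8% between genes and 2% to 3.66% at promoters. The highest fold enrichments in MEF were in the gene bodies of Secisbp2l (23.5-fold, chromosome 2, 125765908 to 125767117 in mm10) and Pigf (22.3-fold), and at an intergenic peak assigned to Irs1 (16.9-fold), the gene of an insulin receptor substrate. These folds are the authors' own scores. At 1 and 5 dpi the strongest peak was intergenic, assigned to G530011O06Rik (59.4-fold and 61.8-fold). Erdr1 was among the top 3 at 1, 5 and 7 dpi and in primary neurons, and a peak upstream of Txndc11, a thioredoxin domain gene, led at 3 dpi (44.9-fold). MEF held 2165 peaks, induced neurons 1886, 1447, 3918 and 14091 at 1, 3, 5 and 7 dpi, and primary neurons 6636. These numbers depend on depth and threshold and were not tested.

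Promoters of germline genes, which work in meiosis and gamete formation, carried peaks in the induced neurons and primary neurons but in no MEF peak. Of 52 germline genes, 0 had a promoter peak in MEF, 8 at 1 dpi, 1 at 3 dpi, 16 at 5 dpi, 8 at 7 dpi and 5 in primary neurons. All but the values of MEF (percentile 45.4) and 3 dpi (97.3) were at percentile 100 of random lists. With peaks of any class assigned to a gene, germline genes were at percentile 99.8 at 1 dpi, 100 at 5 dpi and 98.1 at 7 dpi, but at 40.5 in MEF, 69.2 at 3 dpi and 88.4 in primary neurons. Dazl, an RNA-binding protein of germ cells chosen after its value was seen, had a promoter peak of 9.18-fold at 1 dpi, 13.6-fold at 5 dpi, 6.78-fold at 7 dpi and 7.58-fold in primary neurons. Of 48 imprinted genes, 1 had a promoter peak in MEF (Kcnq1ot1), 2 at 1 dpi (Plagl1 and Peg10), 2 at 3 dpi (Peg10 and Mest), 8 at 5 dpi, 5 at 7 dpi and 4 in primary neurons.

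With peaks of any class, which lie mostly outside promoters, further lists stood apart, the neuronal and fibroblast ones among them. The random lists were not matched on gene length or on the span between genes. Gene size was therefore not separated from methylation in these calls. Genes of neuronal structure and synapse had a peak in 12 of 53 cases in MEF (percentile 99.98), 33 at 7 dpi (percentile 100) and 18 in primary neurons (percentile 99.9). At 7 dpi so did 25 of 50 neuronal fate factors (percentile 99.9), 37 of 60 channels and receptors (percentile 100) and 28 of 50 fibroblast genes (percentile 100), and in primary neurons 28 channels and receptors (percentile 100) and 18 fibroblast genes (percentile 99.9). None of these calls was kept with promoter peaks alone, where the percentiles of neuronal structure were 45.2 in MEF, 96.2 at 7 dpi and 84.0 in primary neurons. Few background genes had a promoter peak, 51 in MEF, 453 at 7 dpi and 163 in primary neurons. In MEF 0 of 53 members gave the 45.2, so calls could be lost for lack of promoter peaks. Olfactory and vomeronasal receptors had fewer peaks than random lists in all 6 libraries, from 29 of 1479 at 1 and 3 dpi to 223 at 7 dpi, and did not stand apart with promoter peaks alone. KRAB-like zinc finger genes had more at 1 dpi (46 of 371, percentile 100) and 5 dpi (63, percentile 100), calls not kept with promoter peaks alone (86.0 and 94.0).

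More peaks of the induced neurons overlapped peaks of primary neurons than peaks of MEF at every time. The shares overlapping primary neurons were 49.0%, 55.4%, 38.8% and 8.42% at 1, 3, 5 and 7 dpi, and those overlapping MEF were 16.7%, 20.7%, 11% and 2.76%. Primary neurons have more peaks than MEF, 6636 against 2165. With the 1447 peaks of highest score from each library, the shares were 31.1%, 30.1%, 35.5% and 21.0% with primary neurons and 14.9%, 15%, 16.0% and 10.6% with MEF. Of the MEF peaks, 189 (8.73%) overlapped a peak in all 5 other libraries and 1609 (74.3%) in none. MEF also had the smallest share of peaks over 10-fold, 1.71%. The shares were 12.5%, 8.78%, 15.9% and 3.26% at 1, 3, 5 and 7 dpi and 3.22% in primary neurons. Equal numbers of peaks do not correct for this, so weaker enrichment in MEF was not separated from a likeness to primary neurons.

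The listed promoter regions were mostly lower than MEF at 1, 3 and 5 dpi. At these times the values were whole reads without visible scaling, and library totals were not analysed. A difference in depth was therefore not separated from a difference in methylation. The authors listed 2990 lower and 516 higher regions at 1 dpi, 3777 and 1439 at 3 dpi, 3018 and 1134 at 5 dpi, 2475 and 3576 at 7 dpi, and 4461 and 6173 in primary neurons. The lower share was 85.3% (95% interval 84.1 to 86.4) at 1 dpi, 72.4% (71.2 to 73.6) at 3 dpi, 72.7% (71.3 to 74.0) at 5 dpi, 40.9% (39.7 to 42.2) at 7 dpi and 42.0% (41.0 to 42.9) in primary neurons. The direction at 7 dpi turned with the processing: the lower share was 51.5% with the test on unscaled reads and 63.0% with the same minimum of 13 reads in both directions. In primary neurons the share was 33.5% with that minimum. Both alternatives could remove listed regions but not add any. With p of at most 1e-05 the lists held 580 to 1643 lower and 214 to 2636 higher regions. In 79.7% to 97.2% of the regions of each list the lower library had 0 reads.

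**Figure D1:**
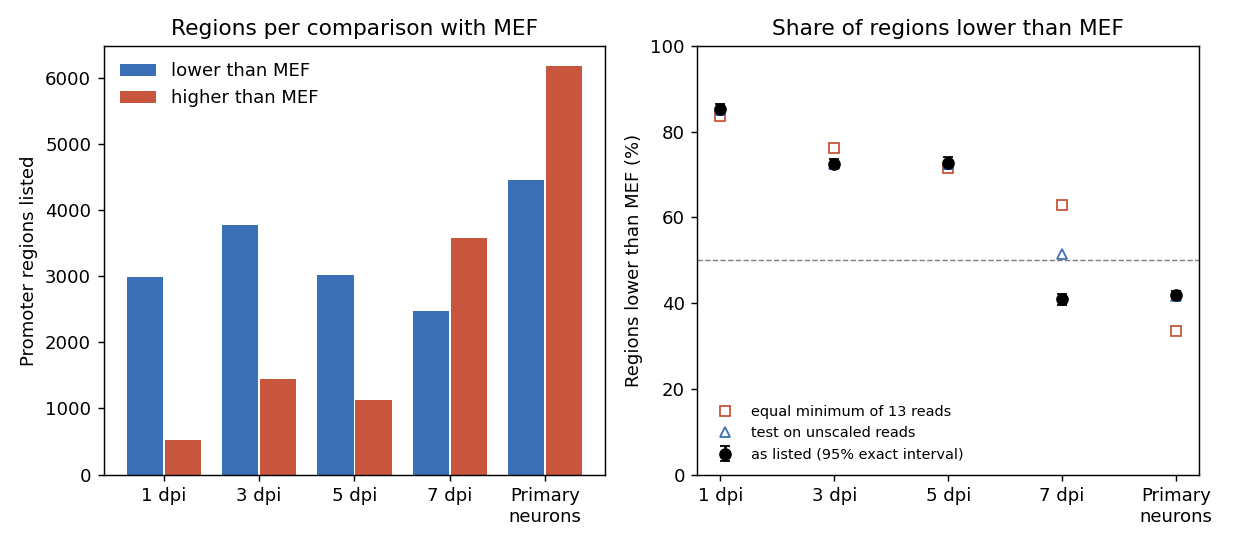
Left, number of promoter regions listed lower (blue) and higher (red) than MEF in each library, 1 library per group. Right, percent of regions that were lower as listed (black, with 95% exact intervals), with an equal minimum of 13 reads (red squares) and with the test on unscaled reads (blue triangles); at 7 dpi the share moves from 40.9% to 63.0% and 51.5%, across the dashed line at 50%.

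The comparison of 1 dpi with MEF asked how promoters differed at the earliest time. Regions of 2784 genes were lower than MEF. The largest differences were at Sertad4 (1 read against 39 in MEF, 39-fold lower, interval 6.60 to 1579, chromosome 1, 192853181 to 192853620, upstream of the TSS), Ppp2r5d, a regulatory subunit of protein phosphatase 2A (1 against 38), Hsd17b11, a hydroxysteroid dehydrogenase (1 against 34), Iws1, a transcription elongation factor (3 against 39), and Tdrd6, a germ cell gene (3 against 34). Regions of 465 genes were higher. D1Pas1, a testis RNA helicase, had 76 reads against 2 in MEF (38-fold, 10.2 to 319), and Sycp2, part of the synaptonemal complex of meiosis, 54 against 1 (54.0-fold, 9.29 to 2172, chromosome 2, 178407081 to 178407900, spanning the TSS). Sec1 followed with 52 against 2, Chpf2, a chondroitin synthesis gene, with 37 against 2, and the cadherin Fat1 with 37 against 0 (at least 12.3-fold). In the authors' deposited table the log2 fold change of Sycp2 was 5.75 with a q-value of 1.2e-11.

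Among the fixed lists at 1 dpi, 14 of 52 germline genes (percentile 100), 9 of 48 imprinted genes (percentile 100) and 14 of 58 clustered protocadherins (percentile 100) were higher than MEF, while 3, 8 and 9 members were lower. Lower protocadherins stood apart with the equal minimum alone (percentile 98.7). Spo11, which makes the DNA breaks of meiosis, had 24 reads against 1, Kcnq1ot1, an imprinted noncoding RNA, 32 against 3, Pcdha6 33 against 3 and Pcdhgb2 24 against 0. Kcnq1ot1 also had another region lower than MEF (1 against 16, chosen after its value was seen). Of the genes of neuronal structure and synapse, 9 of 53 were lower and 0 higher, among them Ncam1, a neural cell adhesion molecule (2 against 27), and Mapt, which encodes tau (0 against 17, at least 5.67-fold). Of the channels and receptors, 9 of 60 were lower and 1 higher, with Gad2, which makes GABA, at 2 against 18 and Gabrb1 at 1 against 17. Of the neuronal fate factors 4 were lower (Otx2, 0 against 15) and 2 higher (Dlx6, 12 against 0) of 50. Fibroblast genes were lower in 6 of 50 cases, including Col5a2 (1 against 22) and Cnn1 (1 against 18). The neuronal and fibroblast lists did not stand apart from random lists, except that lower genes of neuronal structure did with the stricter p (percentile 98.4) and without regions of 380 bp (97.7). The gene of the demethylating enzyme Tet1 was lower (1 against 17), as was that of the maintenance methyltransferase Dnmt1 (0 against 14). Olfactory and vomeronasal receptors were more often lower than random lists (218 of 1479, percentile 100) and less often higher (13, percentile 0.275). With the stricter p neither call was kept (92.6 and 6.32), and the shortage of higher genes also ended with the equal minimum (2.97).

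At 3 dpi, regions of 3480 genes were lower than MEF. Grb2, an adaptor of growth factor receptors, had 3 reads against 42 in MEF (14.0-fold lower, 4.47 to 70.6, chromosome 11, 115706481 to 115706900), and Mobp, a myelin gene, had 0 against 38 (at least 12.7-fold). Zmym1 (3 against 36), Cldn14, a claudin of tight junctions (2 against 35), and Htatsf1 (2 against 35) followed. Regions of 1380 genes were higher. Zbtb24, a zinc finger gene mutated in a syndrome of DNA hypomethylation, had 43 reads against 3 (14.3-fold, 4.59 to 72.2, chromosome 10, 41451701 to 41452160, within the gene). Xist, the noncoding RNA of X inactivation, had 29 against 3, and Gtpbp4, Nt5dc2 and Tmem206 each had 28 against 0 (at least 9.33-fold).

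Of the lists at 3 dpi, higher regions were found for 7 of 52 germline genes (percentile 99.0), 7 of 48 imprinted genes (percentile 99.4), 6 of 39 HOX genes (percentile 99.2) and 30 of 371 KRAB-like zinc finger genes (percentile 99.0). Lower regions were found for 9, 9, 8 and 62 members of these lists, in each more than the higher ones. Gnas had 26 reads against 3, Hoxa5 20 against 0 and Zfp93 27 against 0. Piwil1 (2 against 24) and Stk31 (0 against 22), both germline genes, were lower, as were 9 germline genes in all. The germline call of higher genes ended with a background of genes in any table (percentile 94.5), and the imprinted call ended with that background (96.1) and with the stricter p (94.5). The HOX call ended with the stricter p (96.4), the equal minimum (85.4) and without regions of 380 bp (92.6), and the KRAB-like call with the background of table genes (93.4) and the stricter p (92.0). Only 4 of 58 protocadherins were higher, a number that did not stand apart. Genes of neuronal structure were lower in 10 of 53 cases (Ncam1, 0 against 27) and higher in 1. Channel and receptor genes were lower in 9 of 60 cases (Gad2, 0 against 18) and higher in 5, and fibroblast genes were lower in 8 of 50 cases (Cd44, 1 against 16) and higher in 1. The fate factor Neurod6 was higher (21 against 0) and Otx2 lower (1 against 16). Tet1 was lower (0 against 17) and Dnmt3l, a cofactor of de novo methylation, higher (13 against 0). Olfactory and vomeronasal receptors were lower in 257 of 1479 cases (percentile 100).

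At 5 dpi, regions of 2816 genes were lower than MEF, led by Sertad4 (1 read against 39, 39-fold), Zmym1 (1 against 36), Iws1 (2 against 39), Mobp (2 against 38) and Ppp2r5d (2 against 38). Regions of 1012 genes were higher. Ipo4, a nuclear import receptor, had 54 reads against 1 in MEF (54.0-fold, 9.29 to 2172, chromosome 14, 55633621 to 55634140), Sec1 53 against 1, Sycp2 49 against 1, and the multi-copy genes Erdr1 and Tmem181b-ps 53 against 1 and 70 against 4. Germline genes were higher in 19 of 52 cases, imprinted genes in 15 of 48 and protocadherins in 12 of 58 (percentile 100 each). Lower regions were found for 5, 9 and 9 members of these lists (percentiles 42.5, 95.6 and 87.9). Sohlh2, a transcription factor of germ cells, had 35 against 1, Plagl1, an imprinted zinc finger gene, 44 against 2, Peg10 39 against 4 and Pcdha1 24 against 0. Keratins and keratin-associated genes were higher in 11 of 110 cases (percentile 99.8; Krt75, 24 against 0).

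Genes of neuronal structure at 5 dpi were lower in 7 of 53 cases and higher in 2, channels and receptors lower in 8 of 60 and higher in 1, and fibroblast genes lower in 6 of 50 and higher in 1, none of which stood apart. Ncam1 had 3 reads against 27, Mapt 1 against 17, Gad2 0 against 18 and Col5a2 0 against 22. Tet2, a gene of a demethylating enzyme, was higher (19 against 0). Olfactory and vomeronasal receptors were lower in 231 of 1479 cases (percentile 100) and higher in 31 (percentile 0.01). KRAB-like zinc finger genes were lower in 53 of 371 cases (percentile 98.5; Zfp92, 1 against 21), a call that ended with a background of genes in any table (82.5) and with the equal minimum (97.0).

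At 7 dpi, regions of 2338 genes were lower and regions of 3267 genes higher than MEF. The lower genes were led by Sfi1, a multi-copy centrosomal gene that also had a higher region in all 5 comparisons (1 read against 42 in the lower one), Sertad4 (0 against 39, at least 9.75-fold on the scaled values), Crx, a transcription factor of photoreceptors (1 against 39, 29.4-fold, 4.95 to 1184, chromosome 7, 15880821 to 15881260), Ppp2r5d (1 against 38) and Iws1 (2 against 37). The higher genes were led by Apoa4, an apolipoprotein (42 against 3, 18.7-fold, 5.97 to 94.2), D1Pas1 (39 against 0, at least 17.3-fold), Osbpl1a (39 against 2), Polr1a, the largest subunit of RNA polymerase I (36 against 0, at least 16.0-fold, chromosome 6, 71909541 to 71910000), and the growth factor gene Gdf1 (34 against 0). Which direction held more regions depended on the read minimum and the scaling, as given above.

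Germline genes at 7 dpi were higher in 18 of 52 cases, imprinted genes in 16 of 48 (percentile 100 each) and protocadherins in 14 of 58 (percentile 99.4). Lower regions were found for 8 germline genes (percentile 94.1) and 9 protocadherins (percentile 95.4). Brdt, a testis bromodomain gene, had 53 reads against 6, Sycp2 24 against 0, Peg10 16 against 1 and Pcdha5 20 against 1. The protocadherin call ended with the stricter p (percentile 92.7) and without regions of 380 bp (97.0). Genes of neuronal structure and synapse were higher in 12 of 53 cases (percentile 98.3), among them Dlg2, a synaptic scaffold (16 against 0), and Nrxn3, a presynaptic adhesion molecule (26 against 5), and lower in 7. That call ended with a background of genes in any table (80.8), with the equal minimum of 13 reads (78.0) and with the stricter p (85.7). Grm3, a glutamate receptor gene (18 against 0), was among 8 of 60 channels and receptors that were higher, and 9 were lower. The fate factor Prox1 (15 against 0) was among 7 of 50 that were higher. Fibroblast genes were higher in 7 of 50 cases, including Lox (15 against 0) and Dcn (14 against 0), and lower in 5. Astrocyte genes were higher in 6 of 20 cases (percentile 98.2; Fabp7, 15 against 0), a call that ended under all 4 alternatives tried for lists. Keratins and associated genes were higher in 25 of 110 cases (percentile 99.9), but did not stand apart without regions of 380 bp (97.3). Imprinted genes were also lower in 9 of 48 cases (percentile 98.6), olfactory and vomeronasal receptors in 168 of 1479 (percentile 99.9) and KRAB-like zinc finger genes in 48 of 371 (percentile 99.5). The lower imprinted and KRAB-like calls ended with a background of genes in any table (90.0 and 93.9) and with the stricter p (78.5 and 64.8).

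In primary neurons, the positive control, regions of 4031 genes were lower and regions of 5370 genes higher than MEF. Sertad4 had 1 read against 39 in MEF (41.6-fold lower, 7.07 to 1692), Crx 2 against 39, Mobp 0 against 38, Kcnq1ot1 0 against 36 (at least 12.9-fold, chromosome 7, 143295461 to 143296020) and Ddx19a 0 against 34. Among higher genes, Pcdha7 had 49 against 0 (at least 15.2-fold, chromosome 18, 36975461 to 36975900, within the gene), Syna, a placental syncytin, 48 against 0, Spryd4 46 against 0, and Bglap3, an osteocalcin-related gene, 48 against 3. Germline genes were higher in 23 of 52 cases (percentile 100), imprinted genes in 20 of 48 (percentile 100) and protocadherins in 24 of 58 (percentile 100). Imprinted genes were lower in 11 cases (percentile 92.4), and stood apart without regions of 380 bp (98.2). Protocadherins were lower in 14 (percentile 96.6), and stood apart with the stricter p (99.6). Sohlh2 had 43 reads against 2, Tdrd1, a germ cell gene, 35 against 0, Nap1l5, an imprinted gene, 40 against 1, and Gnas 35 against 1.

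Genes of neuronal structure and synapse were higher than MEF in primary neurons in 20 of 53 cases (percentile 99.9; Nrxn3, 31 against 1) and lower in 10 (Ncam1, 0 against 27). With a background of genes in any table this list no longer stood apart (percentile 90.0). Fate factors were higher in 16 of 50 cases, with Dlx2 at 24 against 2. Their percentile, 97.6, was so close to the limit that another random draw might change its side, which was not tried. The call ended with the background of table genes (76.2) and the stricter p (75.2). Channels and receptors were higher in 11 of 60 cases (Kcnj6, 31 against 2) and lower in 10, and fibroblast genes higher in 12 of 50 (Dcn, 23 against 0) and lower in 9 (Col5a2, 0 against 22). The methyltransferase gene Dnmt3b was higher (21 against 0) and Tet1 lower (0 against 17). Olfactory and vomeronasal receptors were both lower (293 of 1479, percentile 100) and higher (338, percentile 99.1) more often than random lists, through different genes or regions, and the higher call ended without regions of 380 bp (72.0). Germline genes were also lower in 14 of 52 cases (percentile 98.6), a call that ended with the background of table genes (84.0), the stricter p (72.0) and the equal minimum (78.1).

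**Figure D2:**
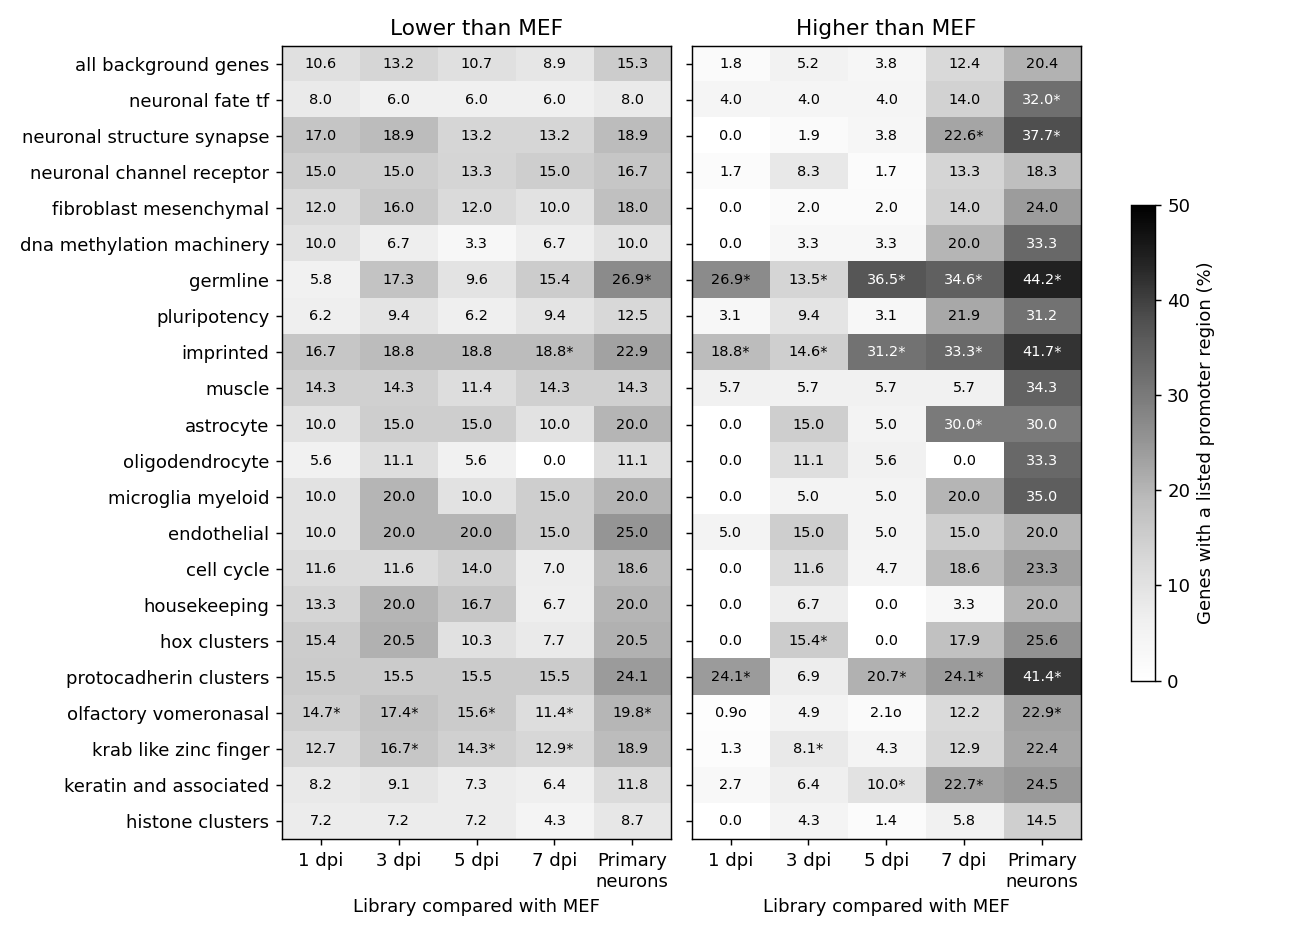
Percent of the genes of each fixed list with a promoter region listed lower (left) or higher (right) than MEF, for each library compared with MEF, 1 library per group; the first line is the share among all background genes. A star marks lists in the upper 2.5% of 10000 random lists and a small o those in the lower 2.5%; among higher genes germline and imprinted genes are starred in all 5 comparisons and protocadherins in 4.

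Genes listed as lower in every one of the 5 comparisons outnumbered those listed as higher in every one. Among background genes, regions of 1029 were lower than MEF in all 5 comparisons, where independent lists of these sizes would share 0.53, and regions of 38 were higher in all 5, against 0.0236. Genes lower in all 5 included Iws1, Psma5, a proteasome subunit (1, 0, 0, 0 and 0 reads against 31 in MEF each time), Cd109 (1, 0, 1, 0 and 0 against 29), Senp7, Syne3 and Taldo1. Genes higher in all 5 included Syna (21, 21, 23, 22 and 48 reads against 0), Gnas, Nt5dc2, Sp110, Dnajb8, Hus1b, Pabpc2, Sycp2 and Mob1b. Of the genes lower at 1, 3, 5 and 7 dpi, 90.8%, 88.7%, 90.8% and 88.0% were also lower in primary neurons, 5.76 to 5.94 times the number of independent lists. Of the higher genes 50%, 35.3%, 42.2% and 28.7% were also higher there, 2.45, 1.73, 2.07 and 1.40 times. By overlap of regions the higher shares were 25%, 12.6%, 19.7% and 8.36%. With a background of genes in any table the ratios were 3.56 to 3.67 for lower genes, and 1.51, 1.07, 1.28 and 0.869 for higher genes at 1, 3, 5 and 7 dpi. Opposite directions in 2 comparisons shared 1.15 to 1.92 times as many genes as independent lists. Part of the excess may come from the shared MEF library, which cannot be split. The number lower in all 5 was 107 with the stricter p, 339 without regions of 380 bp and 1637 without the 7 dpi comparison, and the number higher in all 5 was 9 with the stricter p, 21 by overlap of regions and 68 without 7 dpi.

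**Figure D3:**
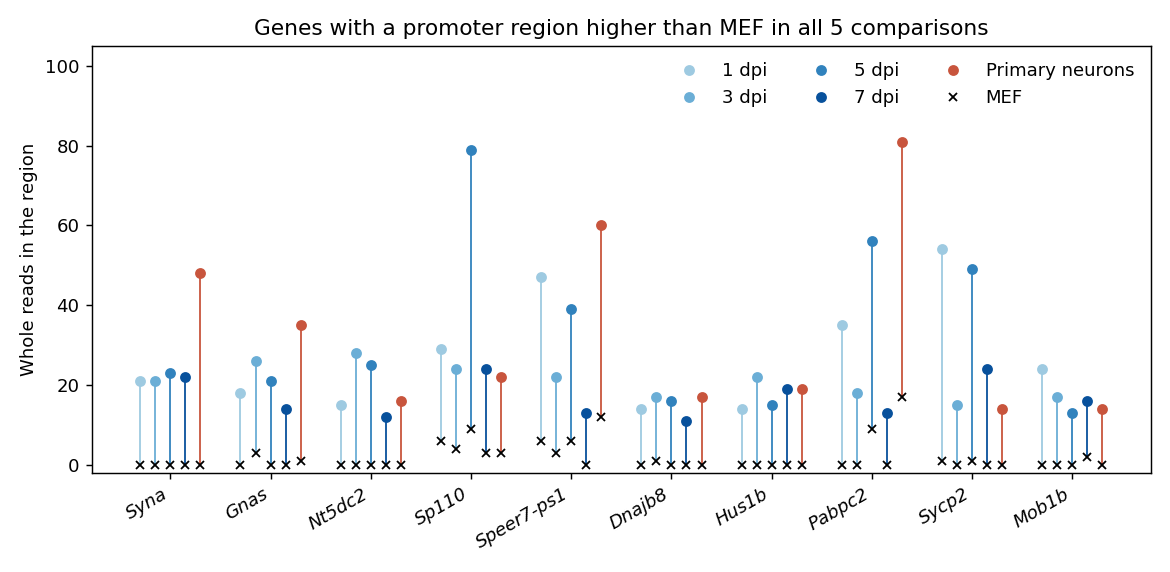
Whole reads in the promoter region of the 10 genes named as higher than MEF in all 5 comparisons, with 1 dot per library and a cross for MEF in the same region; 1 library per group, so no error is drawn. MEF values differ between comparisons because the regions differ; Syna has 21 to 48 reads against 0 in MEF.

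Over the course of the conversion, a larger share of lower genes than of higher genes was listed again at the next time. Of the genes lower at 1, 3 and 5 dpi, 81.9%, 67.5% and 55.9% were lower at the next time. Of the higher genes 28.6%, 17.1% and 33.2% were higher at the next time. With the stricter p these shares were 68.9%, 49.0% and 47.8% for lower genes, and 18.5% (1 to 3 dpi) and 22.7% (5 to 7 dpi) for higher genes. Every lower call rests on the reads of the same MEF library, which favours recurrence. Higher genes listed at exactly 1 time numbered 4128, at 2 times 621, at 3 times 173 and at all 4 times 51, and lower genes 867, 1118, 1317 and 1077. The genes higher at 1 and 5 dpi shared 251 members (17.9 for independent lists), more than 1 and 3 dpi (132). Fat1 was higher at all 4 times (37, 17, 44 and 11 reads) and Amz2 lower at all 4 (0, 3, 1 and 1 reads against 32).

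Lower regions lay on both sides of the TSS, with 47.2% to 49.0% centred upstream. Higher regions at 1 dpi lay upstream in 34.3% of cases and at 5 dpi in 40.8%, against 48.4% to 48.6% in the other 3 comparisons. Few regions overlapped a called peak: 0.92% to 1.86% of lower regions overlapped a MEF peak, and 14.0%, 1.74%, 11.7%, 12.5% and 2.58% of higher regions at 1, 3, 5 and 7 dpi and in primary neurons overlapped a peak of their own library. Peaks of exactly 480 bp, the commonest and shortest length, made up 76.7% of MEF peaks, 7.74%, 20.8%, 10.2% and 78.8% at 1, 3, 5 and 7 dpi and 64.2% in primary neurons. Among promoter regions the length of 380 bp made up 18.6% to 31.5% of lower lists, 6% to 8.53% of higher lists at 1, 3 and 5 dpi, and 34.1% and 33.3% of higher lists at 7 dpi and in primary neurons.

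**Figure D4:**
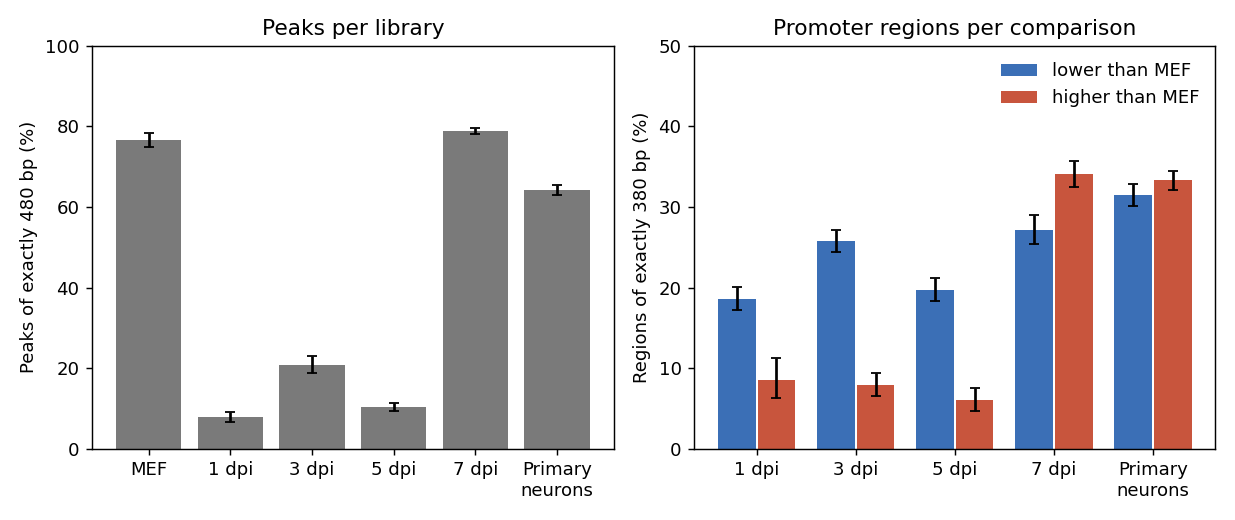
Left, percent of peaks of exactly 480 bp in each library. Right, percent of promoter regions of exactly 380 bp among those lower (blue) and higher (red) than MEF; bars are shares of 1 library or comparison each with 95% exact counting intervals. MEF (76.7%), 7 dpi (78.8%) and primary neurons (64.2%) stand above 1, 3 and 5 dpi.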

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

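All tests weighed here were chosen after the result was seen, except the recurrence of regions of 380 bp.

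The share of promoter regions lower than MEF was below 50% at 7 dpi (40.9%) and in primary neurons (42.0%) and above it at 1, 3 and 5 dpi, a difference between groups that was not tested. The 7 dpi share was 63.0% with the equal minimum of 13 reads and 51.5% with the test on unscaled reads. At 7 dpi both of these could remove higher regions alone. The share was 35.1% with the stricter p and 43.3% without regions of 380 bp, so the contrast with earlier times depends on the processing. Values at 1, 3 and 5 dpi had no visible scaling, so library depth was not separated from the lower shares there. Olfactory and vomeronasal receptors lay at percentile 0.275 among higher genes at 1 dpi and 0.01 at 5 dpi, but at 99.1 in primary neurons, also not tested as a difference. The 1 dpi value was 6.32 with the stricter p and 2.97 with the equal minimum, and the primary neuron value 72.0 without regions of 380 bp. On the mitochondrial chromosome, primary neurons had 6 peaks, MEF 3, 3 dpi 2 and the other libraries 0.

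The lower promoter regions shared by all 5 comparisons might come from the MEF library. Of the 967 shared regions, 275 (28.4%, interval 25.6 to 31.4) had the length that reads stacked at 1 position give, above the 8.53% that was the highest among lists of regions higher at 1, 3 and 5 dpi. The share lay within the 18.6% to 31.5% of the whole lower lists. It was below the 34.1% and 33.3% of higher lists at 7 dpi and in primary neurons. Without regions of 380 bp, 339 of the 1029 genes were still lower in all 5, so stacked reads could account for part of the pattern, how large a part was not settled. A chance property of the single MEF library cannot be told apart from a real difference, since 89.1% of the regions lower at 1 dpi were lower in primary neurons too and there is no second MEF library. Loss of methylation at neuronal genes also stays open: the highest percentile of a neuronal list among lower genes over the 4 times was 94.4, short of the upper limit, although neuronal structure genes at 1 dpi passed it with the stricter p (98.4) and without regions of 380 bp (97.7) and fate factors fell under the lower limit at 3 dpi (0.88 with the background of table genes, 1.98 without regions of 380 bp) and 5 dpi (1.97 with the equal minimum), while 22, 22, 18 and 19 of the 163 members were lower at 1, 3, 5 and 7 dpi.

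The lists of germline and imprinted genes had more higher members than random lists in all 5 comparisons, although most members were not listed at 1 dpi and at 3 dpi more members were lower than higher (9 against 7 in both lists), where lower members also stood apart with the equal minimum (97.7 and 98.5), as did imprinted ones at 5 dpi (99.5). Reads stacked in the induced neuron libraries stay open. Of the higher regions of both lists at 1, 3 and 5 dpi, 6 of 89 (6.74%, 2.51 to 14.1) had a length of 380 bp. Most of them therefore lacked the length that stacked reads gave in the simulation. The share was below the 34.1% of all higher regions at 7 dpi. The whole higher lists at 1, 3 and 5 dpi held at most 8.53%, however, so the test cannot set these genes apart from other higher regions. Promoters listed at several times, such as Sycp2, were counted each time, and the interval treats them as independent. The share was 11.1% (1.38 to 34.7) at 3 dpi alone, 16.7% at 7 dpi and 22.0% in primary neurons. Weaker capture of methylated DNA in the MEF library may contribute. Imprinted genes, taken without measurement to be methylated on 1 allele in fibroblasts as in neurons, were at percentile 99.35 or above at these 3 times. That value, of 3 dpi, was 96.1 with a background of genes in any table, where the germline value was 94.5, and 94.5 with the stricter p. The median fold of peaks was 5.73 in MEF against 7.06, 6.97 and 7.23 at 1, 3 and 5 dpi. At 7 dpi (5.73) and in primary neurons (5.81) it was near that of MEF. The share of peaks over 10-fold was still smaller in MEF, 1.71% against 3.26% at 7 dpi and 3.22% in primary neurons. Both values depend on which peaks were called and do not measure capture directly. Both lists had more higher members at 7 dpi and in primary neurons too, so weaker capture was not settled. Gain of methylation during the conversion was not decided: 26.9% of germline genes were already higher at 1 dpi, and the counting intervals of 1 dpi (15.6 to 41.0) and 3 dpi (5.59 to 25.8) overlap.

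The lengths of peaks set MEF, 7 dpi and primary neurons apart from 1, 3 and 5 dpi. The share of 480-bp peaks did not move steadily from MEF to 7 dpi: it was 76.7% in MEF, 7.74% at 1 dpi and 78.8% at 7 dpi. These shares are the pattern itself, from 1 library per time, so they cannot decide about a steady course of the cells. Stacked reads in these libraries are a candidate explanation: among higher regions at 7 dpi and in primary neurons, those of 380 bp recurred in another list less often than others, by -3.94 percentage points (-5.21 to -2.64). The regions were not matched on reads, so this cannot tell stacks from weak signal. It also covers promoter regions rather than peaks, and leaves out regions of MEF. Neither the fragment lengths nor the depth of the libraries was analysed here, so a difference in library preparation or depth was not tested.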

How the results depend on the processing

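Alternatives with an equal read minimum, unscaled reads, no 380-bp regions, or without the 7 dpi or primary neuron comparison were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Of 1310 alternative values of 429 results, 1091 stayed the same, 112 moved, 75 lists lost and 27 gained their place beyond the limits, and 5 reversed. A fold of at least 4, folds rescaled by 1.5, distinct genes and autosomes moved no region count by more than 1.5 times. They moved no split beyond its interval. In 79.7% to 97.2% of the regions of each list the lower library had 0 reads, and no fold limit or rescaling can remove such a region. The p-values were not computed again after rescaling, so the fold alternatives were nearly settled beforehand and say little. The filter of at least 10 reads removed no region and says nothing. Matching lists on CpG class was not run, since the tables give none. The p that nearly all listed regions reach and the scaling limit what can be listed: the fewest reads in the higher library were 10 to 13, depending on the list. Library depth was not analysed. Except where the alternative itself leaves out items or lowers the limit, the cause was not tested.

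With peak scores above the median of all libraries, MEF kept 937 peaks, 7 dpi 5622 and primary neurons 2824. Overlap of at least 50% of the peak gave 14.4%, 9.78% and 2.48% with MEF at 1, 5 and 7 dpi and 46.6%, 37.2% and 7.81% with primary neurons. Reciprocal overlap of 50% gave 14.4%, 18.6%, 9.62% and 2.42% with MEF and 45.9%, 51.7%, 36.8% and 7.61% with primary neurons at 1, 3, 5 and 7 dpi. With 1447 top peaks each the shares were 14.9%, 15%, 16.0% and 10.6% with MEF and 31.1%, 30.1%, 35.5% and 21.0% with primary neurons. Primary neurons stayed ahead of MEF in each alternative, but none corrects for the small share of strongly enriched MEF peaks.

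With the stricter p (at most 1e-05) the lists held 580, 913, 617, 648 and 1643 lower and 214, 298, 412, 1197 and 2636 higher regions at 1, 3, 5 and 7 dpi and in primary neurons, and lower shares of 73.0%, 75.4%, 59.96%, 35.1% and 38.4%. With an equal minimum of 13 reads, lower regions numbered 1657, 2055 and 1696 at 1, 3 and 5 dpi and 2418 in primary neurons, higher regions 325, 646, 677 and 1455 at 1 to 7 dpi, and lower shares were 83.6%, 76.1%, 63.0% and 33.5% at 1, 3 and 7 dpi and in primary neurons. The 7 dpi share reversed, because the minimum removed higher regions alone, and reversed too with the test on unscaled reads (51.5%, 2329 higher regions). Without 380-bp regions lower shares were 83.8%, 67.9%, 69.4% and 43.3% at 1 to 7 dpi, and higher regions numbered 2357 at 7 dpi and 4115 in primary neurons.

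Genes lower in all 5 comparisons numbered 107 with the stricter p, 339 without 380-bp regions and 1637 without 7 dpi. Genes higher in all 5 numbered 9 with the stricter p, 21 by overlap of regions and 68 without 7 dpi. At 1, 3, 5 and 7 dpi, the shares of lower genes also lower in primary neurons were 89.1%, 87.2%, 89.4% and 85.8% by overlap of regions, 81.2%, 82.4%, 85.0% and 80.6% with the stricter p, and 63.9%, 66.9%, 63.9% and 64.8% without 380-bp regions. The shares of higher genes were 25%, 12.6%, 19.7% and 8.36%, then 41.5%, 24.0%, 29.4% and 16.3%, then 42.4%, 27.1%, 36.0% and 23.0%. The ratio to independent lists reversed for higher genes of 7 dpi and primary neurons with a background of genes in any table (0.869), where the other ratios were 1.51, 1.07 and 1.28 for higher genes at 1, 3 and 5 dpi and 3.56 to 3.67 for lower genes. Lower genes kept to the next time made up 68.9%, 49.0% and 47.8% with the stricter p, and higher genes 18.5% from 1 to 3 dpi and 22.7% from 5 to 7 dpi.

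Among higher genes, germline genes at 3 dpi were at percentile 94.5 and imprinted genes at 96.1 with a background of genes in any table. With the stricter p imprinted genes at 3 dpi were at 94.5 and protocadherins at 7 dpi at 92.7, and without 380-bp regions the latter were at 97.0. Germline, imprinted and protocadherin genes kept their place in the other alternatives at the other times. With promoter peaks alone, the percentile among genes with peaks reversed for keratins in primary neurons (98.3) and protocadherins at 7 dpi (99.0), while of 126 such percentiles 37 lost and 6 gained their place beyond the limits and 81 stayed. Lower calls of the smaller lists could not be kept there, since 0 members still gave percentiles above the lower limit (40.5 for keratins in MEF). Upper calls could be lost for lack of promoter peaks, which only 51 background genes had in MEF.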

Other observations

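No hypothesis is tested in this part, and the genes named follow the rule unless stated.

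Among families found by symbol, keratins and keratin-associated genes were higher than MEF in 3, 7, 11, 25 and 27 of 110 cases at 1, 3, 5 and 7 dpi and in primary neurons. Krt75, a hair follicle keratin, was higher at 3 dpi (18 reads against 0), 5 dpi (24 against 0) and in primary neurons (33 against 0). HOX genes, which pattern the body axis, were higher in 0, 6, 0, 7 and 10 of 39 cases. Hoxa7 was lower at 1 dpi (1 against 17), 3 dpi (0 against 18) and 5 dpi (0 against 18) and, in another region, higher at 7 dpi (29 against 0). Histone cluster genes were higher in 0, 3, 1, 4 and 10 of 69 cases and never stood apart (percentiles 4.08 to 40.3 over both directions). KRAB-like zinc finger genes were lower in 47, 62, 53, 48 and 70 of 371 cases, in the upper 2.5% of random lists at 3, 5 and 7 dpi. The 3 dpi call ended under all 4 alternatives tried for lists (70.5, 96.4, 86.2 and 91.7).

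Genes of the DNA methylation machinery were lower in 3, 2, 1, 2 and 3 of 30 cases and higher in 0, 1, 1, 6 and 10 (percentiles 9.21 to 95.4). Dnmt1 was lower in all 5 comparisons, and at 7 dpi another of its regions was higher (10 reads against 0), values chosen after they were seen. Markers of other cell types did not stand apart, except astrocyte genes at 7 dpi. Muscle genes came just under the upper limit (12 of 35 higher in primary neurons; Myf5, a muscle regulator, 23 against 0). Endothelial genes reached 95, microglia and myeloid genes 93.6 and oligodendrocyte genes 90.2. Under single alternatives some of these lists passed the limit: muscle genes among higher genes in primary neurons (98.9, equal minimum), microglia and myeloid genes among lower genes at 7 dpi (99.4, stricter p) and higher genes in primary neurons (98.0, equal minimum), endothelial genes among higher genes at 3 dpi (98.9, stricter p) and cell cycle genes among higher (99.0) and lower genes (1.74, below the lower limit) at 3 dpi with the equal minimum. Pluripotency genes came just past it among higher genes at 3 dpi with the stricter p. Neuronal fate factors fell under the lower limit among lower genes at 3 dpi (0.88) and in primary neurons (0.87) with the background of table genes. Ptprc, a leukocyte phosphatase, was lower at 1 dpi (0 against 23), 3 dpi (0 against 23), 5 dpi (1 against 23) and in primary neurons (0 against 23). Fibroblast genes reached 74.3, pluripotency genes 93.6 (Fbxo15, 0 against 21 at 1 dpi), cell cycle genes 95.2 and housekeeping genes 85.7.

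Chromosome X, with 4.31% of background genes, held 0.775%, 1.53%, 1.94%, 3.05% and 3.18% of higher regions and 4.62%, 4.26%, 3.98%, 3.31% and 3.61% of lower regions at 1, 3, 5 and 7 dpi and in primary neurons. The peak with the most tags lay at the same place on chromosome 2 in all 6 libraries (98666511 to 98667578 at 7 dpi), with 1030196 to 1744275 tags at the summit. Genes with regions in both directions numbered 61, 264, 125, 376 and 1017 in the 5 comparisons.

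With peaks of any class, lists in the upper 2.5% of random lists beyond those in the report were astrocyte genes at 1 dpi (4 of 20, percentile 98.4), 7 dpi (10) and in primary neurons (7, percentile 97.8), endothelial genes at 7 dpi (10 of 20), pluripotency genes at 1 dpi (5 of 32, percentile 97.7) and imprinted genes at 5 dpi (12 of 48, percentile 99.7) and 7 dpi (21, percentile 98.6). In the lower 2.5% were keratins and associated genes in all 6 libraries, histone clusters in MEF (1 of 69), at 1 dpi (0), at 7 dpi (2) and in primary neurons (2), HOX genes at 5 dpi (0 of 39), 7 dpi (5) and in primary neurons (0), protocadherins in MEF (0 of 58), at 7 dpi (10) and in primary neurons (4), and housekeeping genes at 5 dpi (0 of 30) and in primary neurons (1). With promoter peaks alone, of the lists in the upper 2.5% only the imprinted ones kept their side. Others could lose theirs for lack of promoter peaks, which 63 background genes had at 1 dpi and 453 at 7 dpi. The lists in the lower 2.5% could not keep theirs, because so few genes had promoter peaks. Even 0 members gave percentile 40.5 for keratins in MEF and 15.1 for histone clusters at 7 dpi, so that loss says nothing. As above, gene size was not separated from methylation in calls with peaks of any class.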
